A study of Mus musculus with 9 samples.

How the data were processed

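The series holds RNA-seq profiles of mouse erythroid progenitors from fetal liver of C57BL/6 embryos at embryonic day 13.5 to 14.5. There were 9 libraries, each the single library of its condition. The 3 fresh libraries were BFU-E (burst-forming unit-erythroid, an early progenitor), CFU-E (colony-forming unit-erythroid, a later progenitor) and Ter119-positive erythroblasts. Per the labels' protocols, BFU-E were the 10% of Kit-positive, lineage-negative cells with the lowest CD71 (the transferrin receptor, encoded by Tfrc), CFU-E the 20% with the highest CD71, and erythroblasts were positive for Ter119 and negative for Kit. The progenitor gates excluded cells with Ter119, CD34, CD41 (encoded by Itga2b) or markers of B cells, T cells and myeloid cells on the surface.

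The 6 cultured libraries came from BFU-E sorted by low CD71 alone (CD71 sort, 2 libraries) or by low CD71 and low CD24a (CD71/CD24a sort, 4 libraries). Per the labels' protocols, sorted cells were held for 4 h in serum-free medium with 100 ng/mL stem cell factor, 40 ng/mL IGF-1 and 2 U/mL erythropoietin. They were then divided between treatment arms and kept for another 4 h before RNA was taken. The arms were water or 100 nM dexamethasone (Dex, a synthetic glucocorticoid) in the CD71 sort. In the CD71/CD24a sort they were water, Dex, 333 µM dimethyloxalylglycine (DMOG, an inhibitor of the prolyl hydroxylases that mark HIF alpha subunits for degradation) or both agents. Paired-end mRNA libraries were made with an Illumina kit from 300 bp gel bands.

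The values in the deposited files are RPKM, reads per kilobase of transcript and per M (mega) reads, computed by the authors, with 23041 RefSeq transcript records in each file. The genome build was mm9, per the submitters' processing notes. The aligner, the counting tool, the treatment of reads that match several genes and the use of strand were not given in the sources used here. The 4 CD71/CD24a files held 5954 to 7412 values of exactly 1 and no 0. The other 5 files held 7240 to 8929 values of 0 and 0 values of exactly 1. An exact 1 in the 4 files was therefore read as 0, and keeping it as deposited was an alternative.

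Depth was recovered from the steps between low RPKM values, which are multiples of what 1 read is worth after correction for transcript length. With reads counted up to 10 and a tolerance of 0.1 reads, 66.4% to 69.7% of low values came out whole, against 20% by chance. Transcript lengths came from an annotation of another build (GRCm38), which adds to the misses. The steps gave 18.5 M reads for fresh BFU-E, 23.9 M for CFU-E and 17.5 M for Ter119-positive cells. They gave 11.9 and 13.0 M for CD71 sort water and Dex. They gave 18.5, 19.2, 40.2 and 53.1 M for CD71/CD24a sort water, Dex, DMOG and Dex with DMOG. A level of 3 reads on a 1 kb transcript was 0.0565 to 0.251 RPKM. Exact (Clopper-Pearson) 95% intervals of ratios between libraries were made from the recovered reads and cover counting error only, since PCR copies are not independent molecules.

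Gene symbols came from a RefSeq table of the GRCm38 assembly for 22393 records and from the GENCODE annotation of that assembly for 118, and 530 records had no symbol. No coordinates were used, since the files rest on another build. The records carried 19840 names, and for the 2158 names with several records the record with the highest mean was used. Each library was divided by 1 factor, the median over 6888 genes at 1 or more RPKM in all 9 libraries of the ratio to the geometric mean. The factor was 1.06 for BFU-E, 1.09 for CFU-E, 0.419 for Ter119-positive cells and 1.02 to 1.18 for the cultured libraries. Globin transcripts made up 38.1% of the summed RPKM of the Ter119-positive library. Differences are on the scale of log2(normalised RPKM + 1), which understates the change of low genes. Sequence sharing was the percent of a gene's 32-base words, sampled 1 in 4, that also occur in another gene's transcripts or in a pseudogene, and 10% or more was called shared.

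The 3 fresh libraries have no replicates, so no test was made between them. Genes at 1 or more normalised RPKM in at least 1 of the 2 libraries were compared by a fixed size rule, a difference of at least 2-fold (1 on the log2 scale). A gene list was described by its median difference and by the percentile of that median among 10000 random lists of the same size, drawn in 20 bins of mean expression.

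The cultured libraries were tested with limma 3.58.1 (empirical Bayes with a mean-variance trend) on 9535 genes with a mean of at least 1 normalised RPKM over the 6 libraries, at a Benjamini-Hochberg adjusted p under 0.05. The Dex model held the culture pair (CD71 sort, CD71/CD24a sort, CD71/CD24a sort with DMOG) and Dex. The protocol gives the pairing, since the arms of a sort were divided from the same cells. This left 2 residual degrees of freedom, with 4.31 prior degrees of freedom. DMOG was read from the same fit, over 2 pairs. The combined action of Dex and DMOG was tested as an interaction term with 1 residual degree of freedom. It sets the Dex difference with DMOG against the mean of those without it in both sorts, so a difference between sorts enters it. The Dex by sort term sets the 1 CD71 sort pair against 2 pairs from 1 pool, also with 1 residual degree of freedom. The arms of a sort are parts of 1 pool, so the p-values measure only the spread between these cultures, which may be technical. No count model was used, because the deposited values are not counts.

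There were 22 gene lists, fixed before the data were examined: glucocorticoid-induced genes, HIF targets, glycolysis, oxidative phosphorylation, globins, heme synthesis and iron, red cell membrane, erythroid regulators, stem and progenitor genes, DNA replication and mitosis, cell cycle inhibitors, immediate early genes, inflammatory genes, ribosome biogenesis, sort markers, receptors and oxygen sensing, and markers of macrophages, neutrophils and mast cells, megakaryocytes, hepatocytes, lymphoid cells and endothelium. Some genes stand in several lists. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives.

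The genes named were also set by a rule fixed before the data were examined. For each maturation step they were the 10 genes most higher and the 10 most lower among those at 5 or more normalised RPKM in the higher library. For Dex and DMOG they were up to 12 past the threshold in each direction with the same sign in every pair, filled up to 5 by lowest p where fewer than 5 passed, and for the interaction the 5 lowest p in each direction. They further included up to 4 members of each list with the largest absolute difference, and Kit, Tfrc, Cd24a, Cd34, Nr3c1, Hif1a, Epas1, Egln1, Egln3, Zfp36l2, Epor, Hba-a1 and a beta-globin. The record Hbb-bt stood for Hbb-b1. List members past the threshold that fall outside this rule are also named where they complete a count, and these were chosen after their values were seen.

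The models were checked on simulated data with 200 changed genes among 9535, in 5 simulations, with spreads drawn from limma's own prior. For Dex, 73.7% of 1.5-fold, 96.7% of 2-fold and 100% of 4-fold changes were called, with 45 false calls among 46357 unchanged genes. For DMOG the shares were 47.5%, 91.6% and 99.7%, and for the interaction 7.46%, 53.7% and 100%. The changed genes were drawn from the better-expressed genes alone. The simulated data held no difference of the Dex effect between sorts, so these shares may be too high for the real data. In the list test on 9947 genes of the BFU-E to CFU-E step, 0 of 20 lists with no shift passed the 97.5th percentile, against 19 of 20 with a shift of 0.5.

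The alternatives tried were RPKM without the factor, a pseudocount of 0.1, no filter or a filter at 5, the mean of records sharing a symbol, limma without the trend, each culture pair left out, no pair in the model, the 4 CD71/CD24a libraries alone, exact 1 values as deposited, and genes with under 10% shared sequence alone. The last 2 and a model with a Dex by sort term were added after the data were examined. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.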

Results

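RNA-seq profiles of mouse fetal liver erythroid cells were compared along maturation and after 4 h of treatment of cultured BFU-E with Dex, with DMOG or with both. The set held 3 fresh libraries (BFU-E, CFU-E and Ter119-positive erythroblasts) and 6 cultured BFU-E libraries, with no replicate of any condition. Cultured BFU-E had been taken by low CD71 alone (CD71 sort, 2 libraries) or by low CD71 and low CD24a (CD71/CD24a sort, 4 libraries). Recovered depth ran from 11.9 M to 53.1 M reads per library, lowest in the 2 CD71 sort cultures and highest in the 2 DMOG-treated cultures. Levels are normalised RPKM, and differences between fresh libraries have no replicate check.

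The first comparison asked how transcript levels differ between the early progenitor BFU-E and the later progenitor CFU-E. Genes of the red cell itself stood higher in CFU-E. All 4 expressed globin transcripts, 14 of 20 heme synthesis and iron genes and 14 of 21 red cell membrane genes were at least 2-fold higher, and 0 members of the 3 lists were 2-fold lower. Tfrc, which takes up transferrin-bound iron, was 18.9 in BFU-E and 104 in CFU-E, a ratio of 5.52 (exact 95% interval of counting error 5.25 to 5.80). It encodes CD71, which was gated low in BFU-E and high in CFU-E, so its direction follows the gates and is no separate evidence. The membrane skeleton gene Epb42 was 1.63 and 23.1 and the ammonium channel gene Rhag 16.0 and 99.6. Alpha-globin Hba-a1 was 18.6 and 128 and beta-globin Hbb-bt 14.3 and 74.0, with 68.4% and 62.0% of their sequence shared with other copies, so each copy's own level is uncertain. The 4 globin records form 2 pairs of near-identical values, Hba-a1 with Hba-a2 and Hbb-bt with Hbb-b2. Globin counts, percentiles and list tests, here and below, therefore rest on fewer independent members than listed.

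Stem and progenitor genes stood lower in CFU-E, with 21 of 27 expressed members at least 2-fold lower and 1 higher. Gata2, a transcription factor of stem cells and early progenitors, was 82.9 in BFU-E and 1.26 in CFU-E, Cd34 12.8 and 0.204, and Cd48 25.8 and 1.42. The stem cell factor receptor gene Kit was 175 and 83.0. Of 12 expressed immediate early genes, which encode fast-response transcription factors, 9 were at least 2-fold lower, among them Jun (53.4 and 5.49), Fos (11.5 and 0.535) and Egr1 (10.9 and 0.478). Of 21 expressed glucocorticoid-induced genes 12 were lower and 3 higher. The lower ones included Zfp36 (17.9 and 1.79) and Rhob (13.4 and 2.10), and the transglutaminase gene Tgm2 was higher (12.8 and 60.7). Zfp36l2, an RNA-binding protein gene needed for BFU-E self-renewal, was 244 and 74.0, and the glucocorticoid receptor gene Nr3c1 23.6 and 14.2.

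By the rule of 2-fold, 330 of 9947 expressed genes were higher in CFU-E and 1224 were lower. The largest differences upward were in Scd1, a fatty acid desaturase gene (0.802 and 38.4), Rgcc, Cldn13 (8.14 and 147), Arhgdig, Pdia2, the water and glycerol channel gene Aqp3 (1.27 and 25.7), Tlcd4, the sulfate transporter gene Slc26a1, Mrap and Camsap2. The largest downward were in Vim, an intermediate filament gene (355 and 1.47), the lipid carrier gene Apoe (862 and 13.5), Muc13, the actin-binding gene Coro1a (88.6 and 1.28), Gata2, the immunoproteasome gene Psmb8 (45.6 and 0.442), Rab37, H1f10, Fmnl1 and the leukocyte integrin gene Itgal (32.8 and 0.288).

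Medians of the lists were set against 10000 random lists matched on expression. The globin median of 2.51, the heme median of 1.28 and the membrane median of 1.67 on the log2 scale lay at the 100th percentile, as did DNA replication and mitosis genes with a median of 0.37 (3 of 28 members 2-fold higher, among them the cyclin gene Ccne1 at 25.9 and 99.7). The glucocorticoid-induced median of -1.40, the stem and progenitor median of -1.73, the immediate early median of -1.24 and the median of -1.62 of 6 sort markers (2 higher, 4 lower) lay at percentile 0. Inflammatory genes had a median of -1.20 at percentile 1.55, with 4 of 7 lower, among them Irf1 (4.16 and 0.289). HIF targets lay at percentile 69.6, with 1 of 38 higher and 7 lower. The lower ones held the oxygen sensor gene Egln3 (7.96 and 0.219) and the carbonic anhydrase gene Car9 (4.33 and 0.552). Glycolysis (percentile 43.3, 1 of 17 lower), oxidative phosphorylation (76.7, 0 of 24 at 2-fold), ribosome biogenesis (81.9, 0 of 20), erythroid regulators (7.37, 2 of 18 higher and 1 lower), cell cycle inhibitors (89.8, 1 of 13 higher and 2 lower) and receptors and oxygen sensing (43.0, 1 of 9 lower) lay within the middle 95% of random lists. Among erythroid regulators the erythropoietin receptor gene Epor was 87.0 and 202, and Trim10 1.13 and 16.9. Hif1a was 6.44 and 5.64, Egln1 16.9 and 19.7, and Epas1 0.0477 and 0.0289, under the filter.

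Markers of other blood and liver cells stood higher in the BFU-E library. All 5 expressed neutrophil and mast cell markers, of 20 listed, were at least 2-fold lower in CFU-E (percentile 0), with the granule enzyme genes Mpo at 71.5 and 2.09 and Prtn3 at 24.6 and 1.23. A marker near 0 in CFU-E, such as Ctsg (2.09 and 0.0385), passed the filter through its BFU-E value alone. Such entry favours a lower call in the marker lists of this paragraph. Megakaryocyte markers were lower in 6 of 11 (percentile 0.01), including Itga2b, which encodes the CD41 that the gates excluded, at 44.1 and 2.12. Hepatocyte markers were lower in 5 of 7 (percentile 2.10; Alb 10.0 and 3.74) and endothelial markers in 2 of 3 (percentile 0.24; Pecam1 6.88 and 0.178). Too few members were expressed for a median of macrophage markers (Lyz2 4.44 and 0.913, 28.9% shared sequence) or lymphoid markers (Cd79b 8.14 and 0.0645). With a pseudocount of 0.1 the hepatocyte (percentile 5.50) and inflammatory (9.75) medians lay within the middle 95% of random lists.

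**Figure D1:**
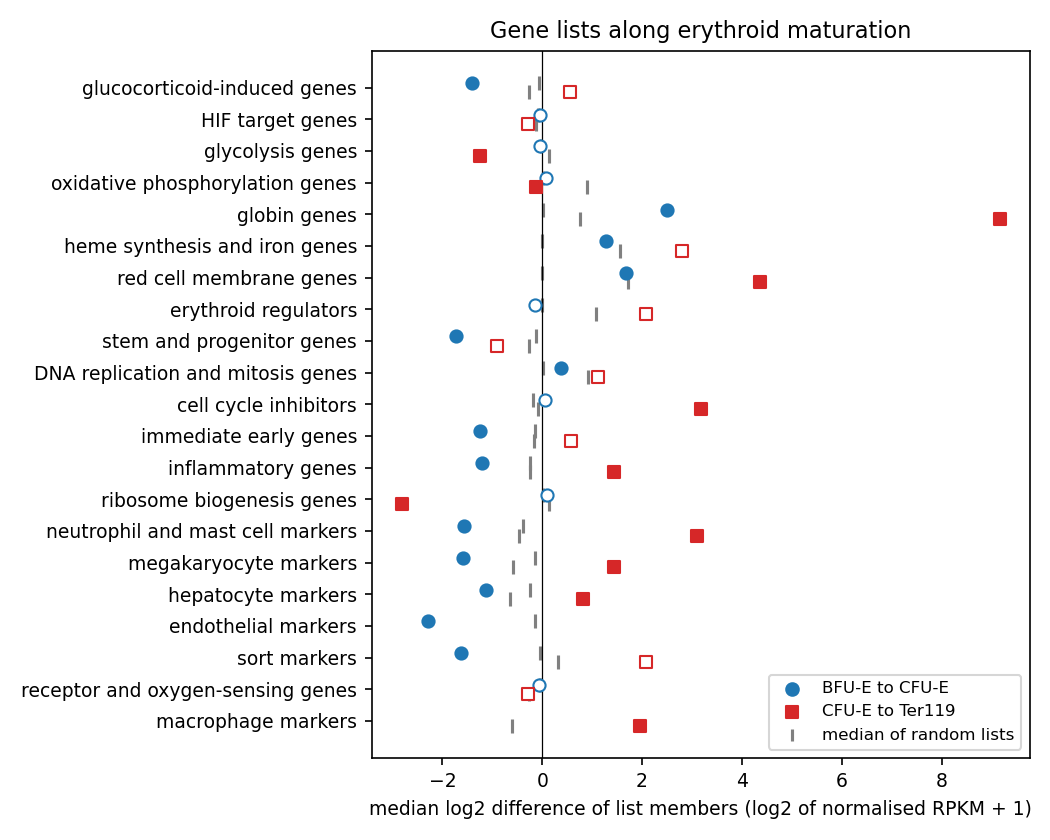
Median log2 difference of the expressed members of each gene list (x axis) from BFU-E to CFU-E (blue circles) and from CFU-E to Ter119-positive cells (red squares), 1 library per population; filled symbols lie outside the middle 95% of 10000 random lists matched on expression, and grey ticks give the random lists' median. Globin genes stand at 2.51 and 9.17 and stem and progenitor genes at -1.73 and -0.90.

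The second step compared CFU-E with Ter119-positive erythroblasts, which are filling with hemoglobin. Relative to the bulk of genes, 7 of 7 expressed globin transcripts, 20 of 21 red cell membrane genes and 18 of 20 heme and iron genes were at least 2-fold higher in erythroblasts. Beta-globin Hbb-bt went from 74.0 to 106489 normalised RPKM and alpha-globin Hba-a1 from 128 to 74090. The anion exchanger gene Slc4a1 stood at 11.8 and 17890, the first heme synthesis enzyme gene Alas2 at 6.33 and 7242, and the mitochondrial iron importer gene Slc25a37 at 37.9 and 6417. Erythroid regulators were higher in 13 of 18 and lower in 3. They included the survival gene Bcl2l1 (8.39 and 1052) and Nfe2 (52.2 and 1477).

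All 20 ribosome biogenesis genes were at least 2-fold lower in erythroblasts (median -2.82), among them Npm1 (249 and 17.7, 29.1% shared sequence) and Polr1b (62.7 and 3.23). Glycolysis genes were lower in 11 of 18 and higher in 2, with Ldha at 603 and 48.2 (19.1% shared sequence), while the glucose transporter gene Slc2a1 was 22.5 and 4316. Cell cycle inhibitors were higher in 10 of 13 and lower in 1, with Btg2 at 3.08 and 310 and Cdkn2d at 0.213 and 59.7. Stem and progenitor genes were lower in 7 of 15 and higher in 4, with Kit at 83.0 and 2.45, Myb at 65.7 and 3.34 and Sox6 at 2.95 and 115. Erythroblasts were gated as negative for Kit, so the direction of Kit follows the gate.

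In all, 2156 of 9530 expressed genes were higher by 2-fold and 2745 lower, so 44.0% of differing genes were higher. Without the scaling factors 788 were higher and 5618 lower, or 12.3%, and leaving them out shifts the log2 differences by a median of -1.21 over genes. The largest differences upward were in Hbb-b2, Hbb-bt, Slc4a1, Alas2, Ypel4 (1.08 and 1686), Hba-a1, Hba-a2, Tmcc2, Fam214b and Fn3k (0.431 and 406). The largest downward were in the folate genes Fpgs and Slc19a1 (each -4.81 on the log2 scale), Kit, Abhd14a, the histone deacetylase gene Hdac7 (48.3 and 1.32), the spermidine synthase gene Srm (334 and 15.1), Dctd, Podxl (72.5 and 2.91), Bzw2 and Stat5a (35.7 and 1.10).

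Against random lists, globin (median 9.17), membrane (4.36) and cell cycle inhibitor (3.19) medians lay at percentile 100, and heme and iron genes (2.80) at 94.7. Ribosome biogenesis lay at percentile 0, glycolysis (median -1.26) at 0.06 and oxidative phosphorylation (median -0.12) at 0.87, though at 8.31 without the factors. Erythroid regulators (2.08) lay at percentile 90.2, stem and progenitor genes (-0.90) at 6.34, HIF targets (-0.29, 9 of 35 higher and 10 lower) at 30.8, inflammatory genes (1.43, 4 of 6 higher, 1 lower; Socs3 at 0.0766 and 99.8) at 99.5, sort markers (2.08, 3 of 5 higher, 1 lower) at 96.6, and receptors and oxygen sensing (-0.28, 1 of 8 higher) at 48.8. Medians of 4 lists were above 0 with the factors and below 0 without them. These were glucocorticoid-induced genes (0.55 and -0.58, 9 of 19 higher and 5 lower, percentile 96.8, with Dusp1 at 6.68 and 156), DNA replication and mitosis (1.11 and -0.23, 16 of 28 higher, percentile 63.1), immediate early genes (0.57 and -1.16, 4 of 8 higher and 3 lower, percentile 87.8) and hepatocyte markers (0.81 and -0.13, 2 of 6 higher, percentile 98.3). The respiratory chain gene Ndufa1 (1.33 and -0.03) and the HIF partner gene Arnt (1.13 and -0.18) also changed sign. Without the factors the medians of heme and iron genes (percentile 99.5), erythroid regulators (97.6), glucocorticoid-induced genes (98.3) and sort markers (97.51) lay outside the middle 95% of random lists and that of hepatocyte markers (97.35) within it, and with a pseudocount of 0.1 glucocorticoid-induced genes (97.9) and stem and progenitor genes (0.14) lay outside it.

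Markers of white blood cells accompanied the erythroblast profile. All 11 expressed neutrophil and mast cell markers, of 20 listed (median 3.10, percentile 100), and all 9 expressed macrophage markers (1.97, percentile 100) were at least 2-fold higher than in CFU-E with the factors. All but Mpo and Prtn3 passed the filter through their Ter119 value alone, which favours a higher call. The mast cell genes Cpa3, Cma1, Mcpt4, Ms4a2 and Fcer1a lay under the filter, at 0 to 0.158 RPKM as deposited in the Ter119 library. The median therefore does not speak for mast cell genes as a group. Mpo was 2.09 and 57.3, S100a9 0.554 and 49.1, and the complement gene C1qb 0.218 and 10.1. Megakaryocyte markers were higher in 5 of 9 and lower in 1 (1.45, percentile 99.9), with Pf4 at 1.45 and 16.7. Of the lymphoid and endothelial lists only Lck (0.662 and 9.28) and Eng (23.1 and 1.55) were expressed.

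The third comparison asked which transcripts respond to the glucocorticoid Dex within 4 h in cultured BFU-E. Known glucocorticoid targets rose. Of 19 tested glucocorticoid-induced genes 9 rose and 0 fell (11 and 2 adjusted over the list alone), led by the mTOR inhibitor gene Ddit4 (log2 difference 1.95, SE 0.20), the clock gene Per1 (1.57, SE 0.16), the receptor co-chaperone gene Fkbp5 (1.54, SE 0.071) and Tsc22d3, which encodes GILZ (1.31, SE 0.085). Zfp36l2 rose by 1.18 (SE 0.079), from 62.9 to 157 in the CD71 sort and from 32.2 to 66.5 in the CD71/CD24a sort. Tgm2, Mt2, Zbtb16 and Klf9 were the other 4 that rose. Beta-globin fell, Hbb-bt by 1.57 (SE 0.18), from 822 to 371 in the CD71 sort and from 119 to 43.8 in the CD71/CD24a sort, and 3 of 5 globin members fell over all genes and 5 adjusted over the list alone. The 5 include the near-identical pairs Hbb-bt with Hbb-b2 and Hba-a1 with Hba-a2, so fewer of them are independent.

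The largest rises were in Arhgef3, a guanine nucleotide exchange factor gene (2.56, SE 0.087; 2.16 to 15.5 in the CD71 sort), the matrix protease gene Mmp2 (2.47, SE 0.13; 0.162 to 6.67), Ddit4, Zfp1 (1.91), Hopx (1.91), the integrin gene Itgb3 (1.90), the actin regulator gene Enah (1.80), Serpina3g (1.78, 26.7% shared sequence), 0610040J01Rik (1.76), Frmd4a (1.75), the cytokine signalling inhibitor gene Socs1 (1.72) and the glutathione transferase gene Gsta4 (1.68). The largest falls were in Hbb-b2 (-1.58), Hbb-bt (-1.57), Parm1 (-1.37), Magee2 (-1.34), Grtp1 (-1.30), the interleukin-3 receptor gene Csf2rb2 (-1.18, 30.1% shared sequence), the cytokine gene Osm (-1.11), Thbs1 (-1.10), Rasl11a (-1.09), 1 transcript record without a matched symbol (-1.08), Cpd (-1.04) and Cited4 (-0.95). All of these had the same sign in each of the 3 pairs.

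**Figure D2:**
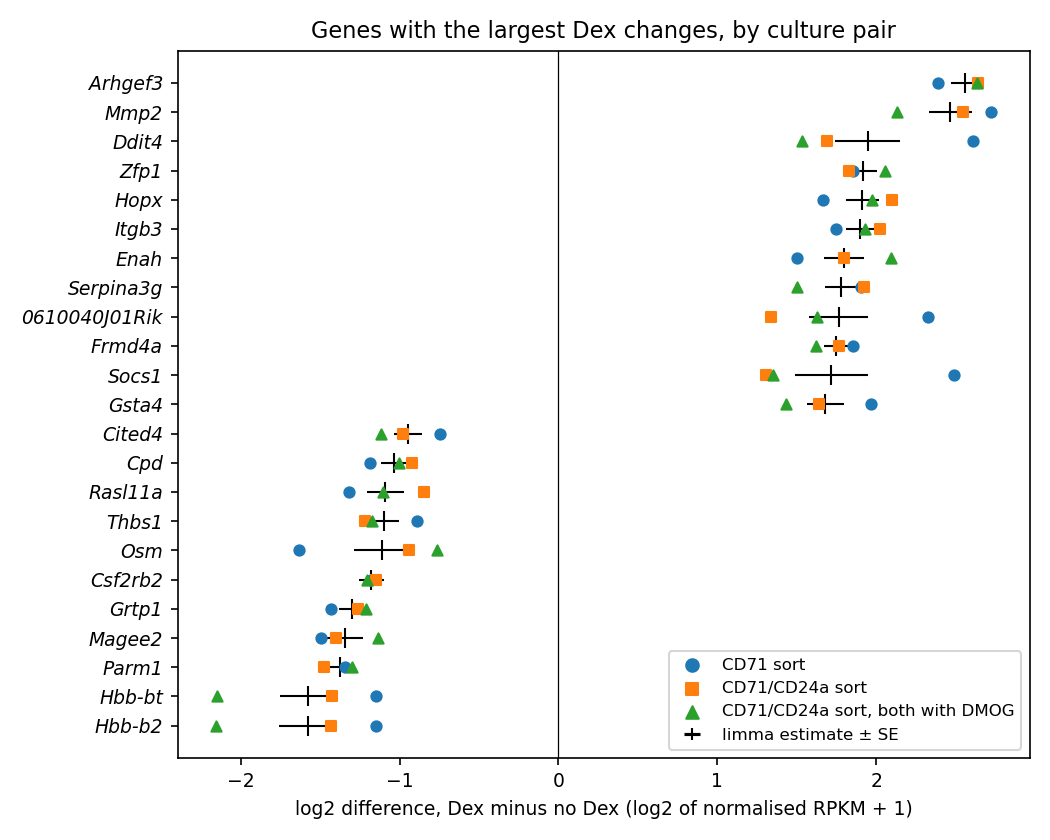
Log2 difference between Dex and no Dex (x axis, log2 of normalised RPKM + 1) of the genes with the largest changes in limma, for each of the 3 culture pairs (coloured symbols) and as the limma estimate with its SE (black crosses). Each gene has the same sign in all 3 pairs, with Arhgef3 at 2.56 and Hbb-b2 at -1.58.

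Among other lists, the oxygen-sensing and receptor genes Hif3a (1.43, SE 0.074) and Egln3 (1.66, SE 0.25) rose, 2 of 9 over all genes and 2 adjusted over the list alone, while Nr3c1 (0.20, adjusted p = 0.283), Egln1 (0.39, adjusted p = 0.211) and Hif1a (-0.09, adjusted p = 0.640) did not pass, and Epas1 lay under the filter. Of 40 HIF targets 6 rose and 0 fell (8 and 1 adjusted over the list alone). They included Ddit4, Egln3, the phosphofructokinase regulator gene Pfkfb4 (1.31), Ndrg1 and Cited2. Of 21 red cell membrane genes 4 rose (5 and 3 fell adjusted over the list alone), namely Cd24a (1.01, SE 0.15), Rhag (0.97), the water channel gene Aqp1 (0.66) and Sptb. Of 20 heme and iron genes the ferritin gene Fth1 rose by 0.79 (2 rose and 4 fell adjusted over the list alone), and Tfrc (-0.55, adjusted p = 0.0542) did not pass. Of 18 erythroid regulators Trim58 rose by 0.73, and Zfpm1 (-0.71) and Lmo2 (-0.69), which encode partners of GATA1, fell (2 rose and 6 fell adjusted over the list alone). Epor was at -0.05 (adjusted p = 0.828).

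Kit rose by 0.76 (SE 0.099), from 45.4 to 93.0 in the CD71 sort and from 43.3 to 65.3 in the CD71/CD24a sort, and Mycn fell by 0.62. These were the 2 of 21 stem and progenitor genes that passed (2 rose and 5 fell adjusted over the list alone). Kit and Cd24a were also the 2 of 6 sort markers that rose (2 rose and 1 fell adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a fell by 0.75, 1 of 11 on its list (0 rose and 3 fell adjusted over the list alone). Of 9 immediate early genes Ier3 rose (0.73) and Jun fell (-0.60), and 2 and 3 did so adjusted over the list alone, where the median of -0.17 and the mean of 0.0064 differ in sign. Socs1 rose among 6 inflammatory genes (1 rose and 2 fell adjusted over the list alone), and the median of -0.22 and the mean of 0.10 differ in sign. Itgb3 rose among 12 megakaryocyte markers (1 rose and 3 fell adjusted over the list alone). Of 18 glycolysis genes Hk1 rose by 0.54 (2 rose and 1 fell adjusted over the list alone), and the median of 0.07 and the mean of -0.01 differ in sign. The median and mean also differ in sign for cell cycle inhibitors (0.03 and -0.18), ribosome biogenesis (0.03 and -1.05e-04) and for megakaryocyte (-0.10 and 0.05), hepatocyte (-0.05 and 0.09) and endothelial markers (-0.11 and 0.04). Of 25 oxidative phosphorylation, 28 replication and mitosis, 20 ribosome biogenesis and 3 endothelial genes 0 passed, over all genes or adjusted over the list alone. Of 4 hepatocyte markers 0 passed over all genes and 1 rose adjusted over the list alone, Apoa1 (0.63, adjusted p = 0.0907 over all genes). Of the other cell markers, Mpo (-0.02), Prtn3 (-0.19) and Cd79b (-0.21) were the tested ones and did not pass, and macrophage markers lay under the filter. Alpha-globin Hba-a1 was at -0.73 (adjusted p = 0.224).

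In limma 133 of 9535 genes rose and 60 fell with Dex at an adjusted p under 0.05, and 691 and 849 at an unadjusted p under 0.05, where chance gives 477 in all. The lists that stood apart from other genes in camera were glucocorticoid-induced genes upward (adjusted p = 1.1e-09), globins downward (adjusted p = 2.7e-05) and receptors and oxygen sensing upward (adjusted p = 0.0021), with adjusted p = 0.627, 0.617 and 0.617 with an estimated correlation. Camera gave adjusted p = 0.0511 for HIF targets and erythroid regulators, 0.0536 for replication and mitosis, 0.138 for sort markers and from 0.191 to 0.921 for the other lists tested. The count rested on the model and the libraries. It was 521 up and 733 down without the CD71 sort pair, 104 and 28 without the CD71/CD24a pair, 161 and 106 without the pair with DMOG, 191 and 106 among genes with under 10% shared sequence, 80 and 36 with a filter at 5, 18 and 3 with no filter on low values, and 3 and 0 with no pair in the model. In the 4 CD71/CD24a libraries alone several lists went both ways or down with Dex: HIF targets 8 up and 7 down, heme and iron 2 and 7, membrane 5 and 2, erythroid regulators 2 and 8, glycolysis 2 and 4, oxidative phosphorylation 2 and 3, stem and progenitor 2 and 5, immediate early 2 and 4, megakaryocyte markers 1 and 4, and replication and mitosis 0 and 6 of 28.

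The fourth comparison asked what the prolyl hydroxylase inhibitor DMOG changes in the CD71/CD24a sort. Ankrd37, a direct HIF target, rose by 3.16 (SE 0.17), from 1.07 to 20.3 without Dex and from 1.14 to 15.8 with it. Narf rose by 1.29 (SE 0.089), from 16.3 to 41.9 and from 16.1 to 40.1. Both are HIF targets, and of the 40 tested HIF targets these 2 rose over all genes and 31 adjusted over the list alone, with 0 falling. Of 18 glycolysis genes 0 passed over all genes and 14 rose adjusted over the list alone. The glucose transporter gene Slc2a1 was 23.7 in water and 56.2 with DMOG (1.32, adjusted p = 0.0519), Aldoc 1.98 and 4.53 (0.94, adjusted p = 0.451) and Pgk1 8.63 and 14.8 (0.80, adjusted p = 0.0915, 57.8% shared sequence).

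The 2 genes were all that passed in the model of 6 libraries (0 fell; 212 and 135 at an unadjusted p under 0.05, where chance gives 477 in all). Next in line were Ak4 (1.15, 11.3% shared sequence), P4ha1, a collagen prolyl hydroxylase gene (1.21), and the histone demethylase gene Kdm3a (1.07), each at adjusted p = 0.0519. Downward the lowest p belonged to Atf7ip (-0.62, adjusted p = 0.195), Cldn13 (-0.60), Rab7 (-0.63, 16.0% shared sequence), Sft2d1 (-0.53, 28.4% shared sequence) and Anapc13 (-0.38), and none passed. Fitted on the 4 CD71/CD24a libraries alone, as planned, limma gave 94 genes up and 45 down, and 529 and 530 at an unadjusted p under 0.05. There 29 of 40 HIF targets, 12 of 18 glycolysis genes and 3 of 9 receptor and oxygen-sensing genes rose, with Egln3 (2.64), Bnip3 (1.52), Ddit4 (1.43), Slc2a1 (1.32), Slc16a3 (0.91) and Kdm3a (1.07) next to Ankrd37 and Narf, and Cldn13, Atf7ip, Rab7 and Txnip (-0.50) among those that fell. In that fit Pf4 (0.90), Ccng2 (0.67), the embryonic globin gene Hbb-y (0.60), Ppox (0.47), Foxo3 (0.40) and Nr3c1 (0.37) also rose, and Hba-a1 (-0.85), Hba-a2 (-0.84), Slamf1 (-0.46) and Cox5b (-0.42) fell. Its 1 residual degree of freedom is the Dex by DMOG interaction of these libraries. Both DMOG libraries were deeper (40.2 and 53.1 M reads) than those without it (18.5 and 19.2 M). An effect of depth therefore cannot be told apart from DMOG.

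In camera HIF targets (adjusted p = 3.1e-60, 39 of 40 with a positive difference), glycolysis (adjusted p = 5.2e-27, 18 of 18) and receptors and oxygen sensing (adjusted p = 0.0096, 6 of 9) moved upward with DMOG against other genes. With an estimated correlation these were adjusted p = 0.254, 0.254 and 0.513. Of 9 receptor and oxygen-sensing genes 3 rose adjusted over the list alone and 0 over all genes, with Egln3 at 2.64 (adjusted p = 0.0915), Egln1 at 0.66 (adjusted p = 0.719), Nr3c1 at 0.37 (adjusted p = 0.933) and Hif1a at -0.02. Adjusted over the list alone 2 of 19 glucocorticoid-induced genes rose (Ddit4 1.43 and Mt2 0.56 had the largest differences) and 1 of 11 cell cycle inhibitors (Ccng2 had the largest, 0.67). In the other lists tested, namely oxidative phosphorylation, globins, heme and iron, membrane, erythroid regulators, stem and progenitor, replication and mitosis, immediate early, inflammatory, ribosome biogenesis, sort markers and megakaryocyte, hepatocyte and endothelial markers, 0 members passed in the 6 libraries over all genes or adjusted over the list alone, and camera gave adjusted p from 0.0751 to 0.980. The globin median of 0.03 and mean of -0.27 differ in sign, as do the membrane median of -0.0088 and mean of 0.0084. Hbb-bt was at 0.14, Kit at 0.23, Tfrc at 0.06, Cd24a at 0.09, Zfp36l2 at -0.09, Mpo at -0.18 and Cd79b at -0.13, each at adjusted p = 0.999.

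**Figure D3:**
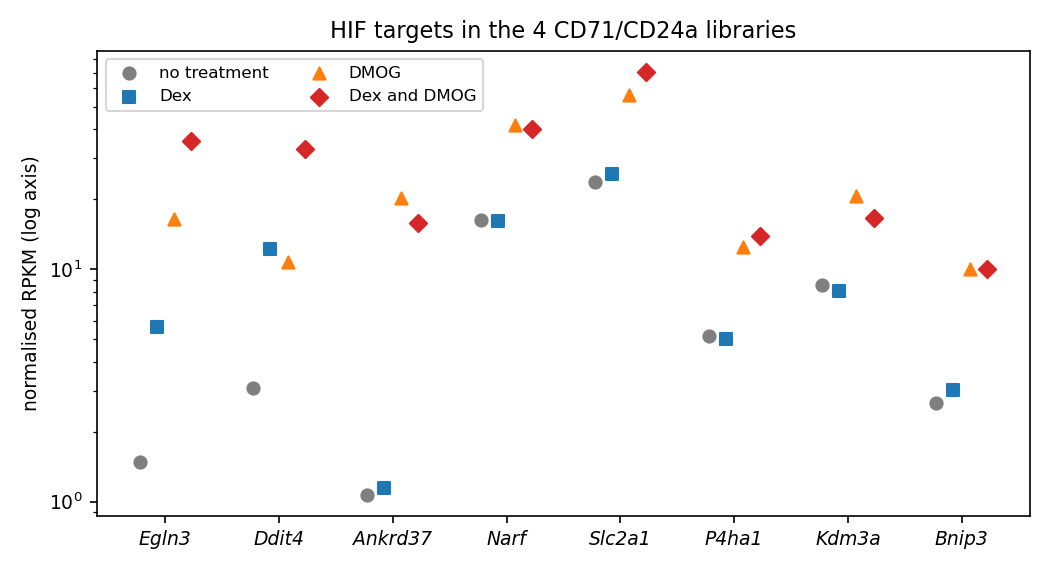
Normalised RPKM (log axis) of 8 HIF targets in the 4 CD71/CD24a libraries, 1 library per condition. Egln3 stands at 1.48 in water, 5.65 with Dex, 16.4 with DMOG and 35.6 with both.

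The fifth comparison asked whether Dex and DMOG together act otherwise than each alone. Ddit4 and Egln3 were high with either agent and highest with both. Ddit4 was 3.09 in water, 12.2 with Dex, 10.7 with DMOG and 32.8 with both, and Egln3 was 1.48, 5.65, 16.4 and 35.6. The Dex difference without and with DMOG in this sort was 1.69 and 1.53 for Ddit4, 1.42 and 1.07 for Egln3, 0.58 and 0.66 for Kit, 1.02 and 1.21 for Zfp36l2 and -1.43 and -2.15 for Hbb-bt. The tested term sets the Dex difference with DMOG against the mean of both sorts without it, so it mixes sort with DMOG. On that term the interaction of Egln3 was -0.88 (SE 0.33, adjusted p = 0.999), and that of Zfp36l2 0.05, Kit -0.14, Nr3c1 0.19 and Hbb-bt -0.87 (adjusted p = 0.677).

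With limma 0 of 9535 genes passed for the interaction, and 152 positive and 123 negative ones had an unadjusted p under 0.05, where chance gives 477. The lowest p included those of Rpl24 (1.04), Dynlt1b (1.70), Tbca (1.17) and 1 record without a symbol (0.85) upward and Rpsa (-1.25, adjusted p = 0.216), Gapdh (-1.19), Ifitm1 (-0.95) and another record without a symbol (-1.51) downward. Of these, Rpl24, Dynlt1b, Tbca, Rpsa and Gapdh had 25.0% to 83.3% shared sequence and Ifitm1 9.23%. With a filter at 5 Rpsa passed, and among genes with under 10% shared sequence Ifitm1 and Dpm3 were among those that did. On simulated data this model called 53.7% of 2-fold and 7.46% of 1.5-fold interactions among better-expressed genes.

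The sixth comparison set the Dex response of the CD71 sort against that of the CD71/CD24a sort, which share no library. Across 9535 genes Pearson's r was 0.395 and Spearman's correlation 0.280, and with genes of under 10% shared sequence alone r was 0.483 (genes are not independent replicates). Genes such as Ddit4 (2.61 in the CD71 sort and 1.69 in the CD71/CD24a sort), Socs1 (2.49 and 1.31), Egln3 (2.48 and 1.42) and Zfp36l2 (1.31 and 1.02) stood higher with Dex in both, while Cd24a was at 0.56 and 1.37. The CD71 sort water library stood apart in the glycolysis gene Pgam1 (log2 Dex difference -2.68, against 0.13 in the CD71/CD24a sort; 37.6% shared sequence). The Dex response of the CD71 sort and the mean DMOG response had a Pearson's r of 0.016 and a Spearman's correlation of -0.0398.

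**Figure D4:**
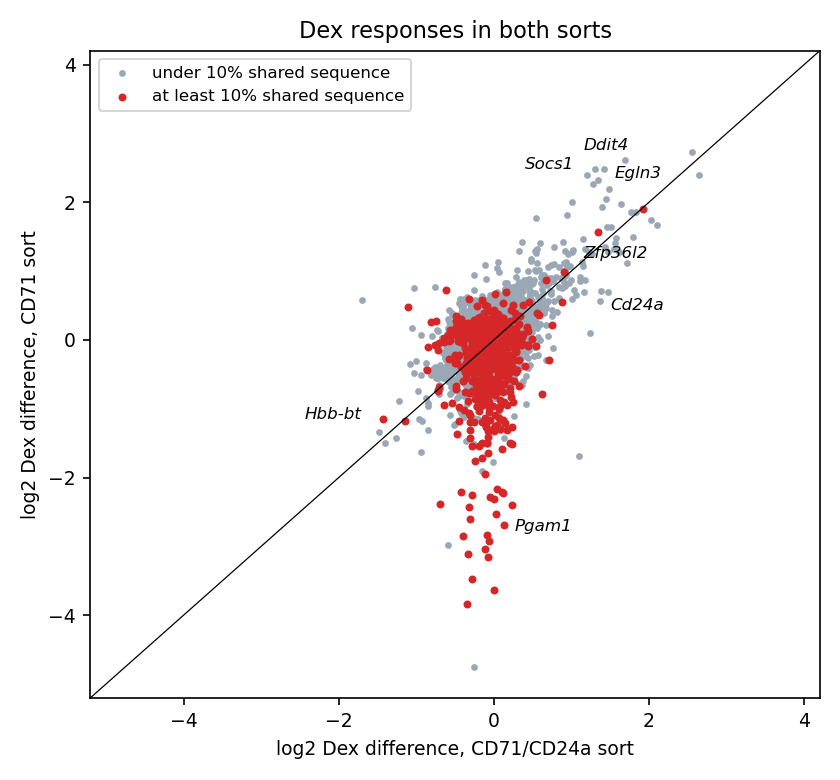
Log2 Dex difference of each tested gene in the CD71/CD24a sort (x axis) and the CD71 sort (y axis), 1 pair of libraries per sort, with genes of at least 10% shared sequence in red. Red genes form a column at large negative values in the CD71 sort, with Pgam1 at -2.68 there and 0.13 in the CD71/CD24a sort.

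The last comparison asked whether genes that rise with Dex or DMOG differ between BFU-E and CFU-E. Of the 119 Dex-induced genes expressed in these progenitors, 79 (66.4%) were lower in CFU-E than in BFU-E, against 57.0% of all genes. Their median log2 difference of -0.37 lay at percentile 0 of 10000 random lists matched on expression, with 39 genes at least 2-fold lower and 18 higher. Between CFU-E and Ter119-positive cells 40 of 102 were 2-fold higher and 30 lower (median 0.21, percentile 92.7), but the median was -0.87 without the scaling factors, and of 253 genes at an unadjusted p under 0.01 80 were higher and 83 lower (median -0.15, percentile 29.2). The Dex-repressed genes lay at percentile 91.2 between BFU-E and CFU-E (99.6 for those with an unadjusted p under 0.01) and at 99.96 between CFU-E and Ter119-positive cells. Of the 2 DMOG-induced genes 1 was lower in CFU-E. Of 69 expressed genes that stood higher with DMOG at an unadjusted p under 0.01, 45 (65.2%) were lower in CFU-E, with a median of -0.32 at percentile 0.39.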

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

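Of the tests below, those of read depth and of other splits of the libraries were written before their results, and all others, including the choice of the 3 patterns, came after. The tests of carried-over erythroblasts, of shared reads in the rest of the genes, of the heme and membrane lists and of the Ter119 scaling factor were each changed after a first result was seen.

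A test of the difference between the sorts, itself added after the files were seen, found 575 of 9535 genes whose Dex effect differed between the CD71 sort and the CD71/CD24a sort at an adjusted p under 0.05 in limma. The CD71 sort has 1 pair, and its difference is set against the spread of 2 pairs from 1 pool, which may be technical, so the count does not show that the sorts would differ in another preparation. Of the 95 tested genes named for Dex, 20 were among them. The CD71 sort minus CD71/CD24a sort difference on the log2 scale was 1.23 for Egln3, 1.16 for Socs1, 1.05 for Egr1, 1.04 for Pfkfb4, 0.997 for Ddit4, 0.94 for Ier2, 0.84 for 0610040J01Rik, 0.72 for Per1, 0.69 for Gata2, 0.63 for Eng, 0.53 for Egln1, -0.59 for Npm1, -0.67 for Cd24a, -0.70 for Ccne2, -0.78 for Osm, -1.16 for Hba-a1 and Hba-a2, -1.23 for Fbl, -1.51 for Cdkn2d and -2.47 for Pgam1.

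The first pattern is this difference between sorts, where several Dex-induced genes stood higher with Dex by more in the CD71 sort. Of 538 called genes with a known share, 33.3% (95% interval 29.3 to 37.4) had at least 10% shared sequence, against 8.79% of the tested genes, so reads shared between copies may explain the difference for those genes. Shared reads are argued against for the 195 genes (36.2%, 95% interval 32.2 to 40.5) with no shared sequence, Egln3, Socs1, Ddit4, Per1, Egln1 and Osm included, and stay open for the 164 (30.5%, against 50.6% of the tested genes) with shared sequence of under 10%. The test of the lower depth of the CD71 sort looked for called genes at low expression. Instead the 359 genes of these 2 classes had a median log2 expression 0.46 above that of the tested genes (95% interval 0.14 to 0.59). The log2 scale used understates changes of low genes and so favours calls at higher expression. The result therefore does not decide on depth. With 1 pair of libraries in the CD71 sort, a biological difference between the sorted cells and a difference between preparations could both be at work.

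The second pattern is the fall of globin transcripts with Dex. Reads moving between the beta-globin copies Hbb-bt and Hbb-b2 are argued against, since their sum fell at least 2.22-fold (4.54-fold at most) in each of the 3 pairs. The values of these copies are near-identical in every library, so the sum acts as 1 record. Reads moving to other globin copies, or between alpha-globin copies, were not tested. Alpha-globin Hba-a1 was at -1.50 in the CD71 sort, -0.09 in the CD71/CD24a sort and -0.59 there with DMOG. Ter119-positive erythroblasts carried over as the source of the beta-globin were tested on 32 abundant erythroblast transcripts in the 3 libraries without Dex. In the CD71 sort, the CD71/CD24a sort and that sort with DMOG, 10, 4 and 7 stood under 0.5 of the level needed. At or above that level stood 17, 24 and 24. Slc4a1 was at 3.12 against 138 needed in the CD71 sort and at 1.15 against 28.6 in the CD71/CD24a sort with DMOG. The values of these 2 libraries argue against carry-over as the source. The 32 include the near-identical Hba-a1 and Hba-a2. In the CD71/CD24a water library Hba-a1 was at 5.12 against 83.0 needed, so the 4 there are not independent and do not decide. The criterion written first, a median of observed over needed levels of at least 0.8, was met (1.15, 7.12 and 5.36), but fresh BFU-E reach that level as well (0.978, 6.74 and 4.73), so it decides nothing. Whether Dex holds back the whole hemoglobin and membrane programme cannot be told apart from an effect on globins alone, since 5 of 41 heme and membrane members rose and 0 fell in the 6 libraries while 7 rose and 9 fell in the 4 CD71/CD24a libraries, and erythroid cells of other stages also stay open.

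The third pattern is the higher level of myeloid markers in the Ter119 library than in CFU-E, for which no biological explanation was tested. The tables argue against the scaling factor as the source, since without it 29 of the 29 macrophage, neutrophil and mast cell markers detected in either library (100%, 95% interval 88.1 to 100), taken with no filter on their level, stood higher in Ter119, and 4 more were 0 in both. Of the 20 that passed the filter, all but Mpo and Prtn3 through their Ter119 value alone, 14 stayed at least 2-fold higher without the factor and the other 6 by less (0.47 for Adgre1 to 0.96 for Ltf, against 1.04 and 1.74 with it), since the factor moves all genes of the library alike. The 95% interval treats the markers as independent, which markers of a few cell types need not be. The bounds set first, under 0.5 or at least 0.75 of the markers past 2-fold, had left 14 of 20 undecided. The gate took Ter119-positive, Kit-negative cells, which would leave out free myeloid cells, so myeloid cells that passed the gate by error and macrophages bound to erythroblasts remain open. The CFU-E gate also excluded cells with myeloid surface markers, which the description of the erythroblast gate does not name, so the libraries were not gated alike.

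Of the 10 ways to divide the 6 cultured libraries into 3 and 3, the Dex division gave 193 genes and the next highest 40, so 1 of 10 gave as many, which is too few divisions for a share under 0.05. The divisions with 40 genes put both arms of a culture pair on 1 side. Among the fewer divisions that kept the arms of every pair apart, each one other than Dex gave 0 genes.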

How the results depend on the processing

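Of the alternatives below, the fits on genes with under 10% shared sequence and with exact 1 values kept were chosen after the files were seen. In the cultured libraries a reversal was a change of sign with the main or the alternative fit past the threshold. Changes of sign among values that passed in neither fit were counted as kept. By this rule no value of a named gene reversed for Dex (957 of 1090 kept their side of the threshold, 88 weaker, 45 stronger), DMOG (768 of 829, 4 weaker, 57 stronger) or the interaction (161 of 163, 2 stronger). From BFU-E to CFU-E 252 of 294 stayed within a fixed bound on the log2 scale and 42 moved past it. That bound was the same for every gene and took no account of counting error. Along maturation a reversal was counted only for genes that differed at least 2-fold in the main comparison. In the next step 162 of 284 kept, 120 moved and 2 reversed without the scaling factors (Ndufa1, CFU-E to Ter119, at -0.0292, and Arnt, CFU-E to Ter119, at -0.177), where 788 genes were higher and 5618 lower by that construction. With a filter at 5, fewer genes were tested: BFU-E to CFU-E genes lower by 2-fold numbered 732, 80 genes rose and 36 fell with Dex, 1 interaction passed and 0% of the 1 DMOG-induced gene was lower in CFU-E. With no filter 18 rose and 3 fell with Dex, 0 rose with DMOG, and the correlation of Dex responses between sorts was 0.367. With no pair in the model 3 rose and 0 fell with Dex. Pairing follows the division of each culture into arms, and limma assumed that each lone library varies like the others. Leaving out 1 Dex pair each gave 104 to 521 rising and 28 to 733 falling genes, the highest without the CD71 sort pair, and 106 falling without the pair with DMOG. Without the CD71 sort pair, which is the fit on 4 libraries, DMOG gave 94 up and 45 down. That pair had no DMOG arm, so it enters the DMOG test of the 6 libraries through the spread and not through the difference. Ankrd37 was at 3.16 in both fits, with SE 0.17 in 6 libraries and 0.10 in 4. Leaving out another pair left no DMOG effect to estimate apart from the sort, and the interaction allowed none. DMOG gave 0 genes up with a pseudocount of 0.1, 7 with the mean of records sharing a symbol and 10 with under 10% shared sequence, where 106 fell with Dex, 3 interactions passed and the correlation between sorts was 0.483. Dex by sort genes numbered 575 (243 up, 332 down), 805 (437, 368) with under 10% shared sequence and 652 (278, 374) with exact 1 values kept. That correlation was 0.283 with the DMOG pair, and the one of Dex and DMOG 0.0658 with orthogonal effects. Of the 6 list results past the threshold in camera, 0 passed with an estimated correlation and 3 passed in fry. Beyond fewer genes or libraries and the part of the CD71 sort pair in the DMOG test, the cause was not tested. Depth limits low genes, with 3 reads on 1 kb at up to 0.251 RPKM. Among better-expressed genes the simulated model called 73.7% of 1.5-fold Dex, 47.5% of 1.5-fold DMOG and 7.46% of 1.5-fold interaction effects.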

Other observations

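The patterns below were chosen after the values were seen, and no test stands behind them. Before any Dex, adult globin transcripts stood lower in cultured BFU-E of the CD71/CD24a sort than in those of the CD71 sort, in 1 library each. Of 9737 genes 140 were at least 2-fold higher and 299 lower in the CD71/CD24a water library. The globin median was -2.78 on the log2 scale and the red cell membrane median -0.49 (4 of 21 members 2-fold lower), both at percentile 0 of random lists. The heme and iron median of -0.24 lay at percentile 4.19 (2 of 20 lower), within their middle 95%. Hbb-bt, an adult beta-globin, was 822 in the CD71 sort and 119 in the CD71/CD24a sort (-2.77), and Hba-a1 was at -5.53, but the embryonic Hbb-y was at -0.56 and Hbb-bh1 at 0.12. The CD71 sort water library stood apart in genes with shared sequence such as Pgam1 (-3.49, 37.6% shared), and Hbb-bt and Hba-a1 share 62.0% and 68.4%, so the globin median is uncertain. Neutrophil and mast cell markers (-1.26, percentile 0.04), inflammatory genes (-0.45, 0.36) and glucocorticoid-induced genes (-0.27, 0.41) also stood lower, while hepatocyte markers (1.04, percentile 100) and megakaryocyte markers (0.54, 99.9) stood higher.

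After 8 h in culture, BFU-E in water differed from fresh BFU-E, with 1 library each. Of 10060 genes 631 were at least 2-fold higher and 911 lower in the CD71 sort, and of 10080 genes 1124 and 1302 in the CD71/CD24a sort, whose gate also differs from that of the fresh cells. The globins went both ways. Hbb-bt was 14.3 in fresh BFU-E, 822 in the CD71 sort and 119 in the CD71/CD24a sort, while Hba-a1 was 18.6, 281 and 5.12, below fresh cells in the second culture. The globin medians of 3.84 (percentile 100) and 1.77 (percentile 99.99) are uncertain, given their shared sequence. Ribosome biogenesis genes stood higher in both (0.49, percentile 99.8, and 0.47, 98.9), Npm1 with 29.1% shared sequence among them (1.46 and 1.80). Glycolysis genes lay just past the middle 95% of random lists in the CD71 sort (0.29, percentile 97.9), where 1 of 18 members was 2-fold higher. In the CD71/CD24a sort they lay within it (-0.02, 59.7), and Pgam1 was at 3.23 and -0.25. Differences between the cultures were not tested for any list. Stem and progenitor genes stood lower in both (-0.89, percentile 0, and -0.91, 0), as did immediate early genes (-0.98, 0.02, and -1.43, 0), with the fast-response gene Jun at 53.4 in fresh cells and 2.04 and 1.69 in culture, glucocorticoid-induced genes (-0.57, 0.14, and -1.02, 0), erythroid regulators (-0.47, 0.19, and -1.01, 0.01), sort markers (-0.96, 0.11, and -0.93, 1.09) and hepatocyte markers (-1.70, 0, and -1.15, 0.31). Megakaryocyte markers (-0.81, 0.27, and -0.31, 24.9) and endothelial markers (-1.41, 0.81, and -0.78) stood lower past the middle 95% of random lists in the CD71 sort alone, and neutrophil and mast cell markers (-0.73, 4.02, and -1.36, 0), cell cycle inhibitors (-0.44, 10.4, and -0.68, 2.31) and receptors and oxygen sensing (-0.33, 12.4, and -0.72, 2.36) in the CD71/CD24a sort alone.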
